A study of Homo sapiens with 18 samples.

How the data were processed

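The samples were 3 T47D-Y lines, with empty vector, WTPR or mCDPR, each given ethanol vehicle or R5020 for 6 hours, with 3 arrays per group and 18 arrays in all, as GEO's labels name them. The sample labels give the R5020 dose as 10 nM, which is used here, and the series description as 10e-8 M. Biotinylated cRNA was hybridized to Illumina HT-12v4 arrays, per the labels. The deposited intensity values are mean bead brightness per probe on a linear scale, not normalized between arrays, per the file headers and the values themselves, which stay well above 0 on every array. The deposited detection p-values give, per the file headers, the standing of each probe against the negative control probes of its array. The deposited table also holds the number of beads and the bead standard error per probe, with a median of 22 beads. Another deposited copy of the signals held the same values (largest difference 0). The log2 values the authors deposited in the series matrix cover 30995 probes. Their method is not stated; they rise with log2 of the intensities within an array (lowest Spearman 0.999999) and share nearly one set of sorted values (mean difference 0.00103), so they were taken as quantile normalized without background correction. Their array medians ran from 7.10 to 7.10, so scale and centring were settled from the values. Probes left out of that matrix were above background on 0 arrays. Scanner software and chip are not given in the sources used here. The full table holds 24 arrays; 6 of them, 24 columns of per-sample values, were not used because no label names them.

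The intensities were background corrected with normexp on the detection p-values, with an offset of 16, quantile normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8). Of 47323 probes, 92 controls were left out, and probes with a detection p under 0.05 on at least 3 of the 18 arrays were kept, 22792 in all. Gene symbols were matched by Entrez gene ID to a reference table of human gene names (names only; 35672 probes matched, 8790 symbols updated), and 3270 probes had no symbol. Each of 16210 genes was represented by 1 kept probe, the one with the highest mean signal; 3699 genes had more than 1. Chromosomes are those of the deposited table, whose genome build is not named.

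A linear model with 6 group means (12 residual degrees of freedom) was fitted with lmFit and eBayes, and 10 comparisons were made: R5020 against vehicle in each line, the differences between lines in that response, the lines against each other with vehicle, and the PR-B lines against each other with R5020. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. For 22 gene lists written by hand from general knowledge, camera tested the shift of each list with at least 3 measured members, with a preset correlation between genes of 0.01 and, as an alternative, one estimated from the data. Camera p-values of these lists were adjusted over the lists of a comparison; that of a further list of NF-kB targets was not adjusted. Choices of groups, comparisons, lists, alternatives and rules were made before the data were examined, except those described below as chosen after seeing the data or the results. The named genes follow a rule: PGR, NR3C1, STAT5A, STAT5B, JAK2, DUSP6 and WNT1 where measured; the 10 largest rises and 10 largest falls among called genes whose groups do not overlap; and up to 4 members per list with the smallest p. For a difference of responses, each R5020 array was set against the mean of its line's vehicle arrays. The text names part of these, and some of them also in comparisons where the rule did not pick them.

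The median signal per array was 113 to 130.2 and 17074 to 19027 probes were detected. For genes detected on all 18 arrays (9512), the median SD between arrays of a group was 0.07 (log2), and the median bead standard error was 0.05. Recovery was tested on simulated data with 200 changed genes among 16210. Far more genes than that were called in every real comparison but that of the vector line. The Benjamini-Hochberg threshold depends on how many genes change, so the shares below do not give the sensitivity of those comparisons. At 2-fold, 95.5%, 97% and 100% of changed genes were recovered for R5020 in the vector, WTPR and mCDPR lines, and at 1.5-fold 74.6%, 70.1% and 62.7%. For the differences of responses, WTPR minus mCDPR, WTPR minus vector and mCDPR minus vector, these were 74.2%, 77.3% and 77.3% at 2-fold and 25.4%, 29.9% and 31.3% at 1.5-fold. For the lines with vehicle, WTPR against vector, mCDPR against vector and mCDPR against WTPR, they were 92.4%, 93.9% and 98.5%, and 67.2%, 65.7% and 62.7%. For the lines with R5020 they were 93.9% and 70.1%. At the smallest fold simulated, below 1.5, between 0% and 17.9% were recovered. Between 5 and 10 unchanged genes were called per comparison.

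The alternatives were no background correction, median scaling, an offset of 50, the authors' log2 values, no filter, a stricter filter (detection p under 0.01 on at least 6 arrays), every kept probe, the replicate number as a block, a term for the 4 arrays whose name ends in _2, the compared groups alone, a variance trend, array weights, a fold minimum of 1.5, the estimated correlation in camera, and leaving out each array. A block for the position of an array in the deposited table and leaving out the 4 _2 arrays were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.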

Results

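Gene expression was measured in T47D-Y cells, a subline of the T47D human breast cancer line that lacks the progesterone receptor (PR). There were 3 stable lines made from these cells. The first carried the empty pSG5 vector, the second expressed wild-type PR-B (WTPR), and the third expressed PR-B with a mutated common docking domain (mCDPR), a short acidic surface through which proteins bind kinases and phosphatases of the MAPK pathway. Each line received ethanol as vehicle or R5020, a synthetic progestin, for 6 hours, at 10 nM by the sample labels (the series description writes the dose as 10e-8 M). Each of the 6 groups had 3 Illumina HT-12v4 arrays, 18 in all. The series title names the question: whether this domain links signalling that depends on the phosphatase MKP3, the product of DUSP6, to regulation of genes through JAK/STAT. The median raw signal per array ran from 113 to 130.2, and between 17074 and 19027 probes per array were detected above background. After the filter on dim probes, 16210 genes were tested. The labels do not say whether arrays of a group came from separate cultures, so p-values here measure only the spread between these arrays, which may be technical. There was 1 line per construct, so a difference between lines belongs to the construct and its clone together.

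Values are log2 fold changes with standard errors (SE) from limma, n = 3 arrays per group, and adjusted p-values are Benjamini-Hochberg over all genes. For a gene whose tested probe was not above background on any array of a group, the fold is given as a lower bound, "at least N-fold". It sets the mean of the bright group against, on each array of the dim group, the higher of the lowest signal among detected probes and the probe's own. Where neither group is above background, no fold is given. For the largest fitted rises and falls named in each comparison, all 3 arrays of one group lay beyond all 3 of the other.

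The PGR probe (chromosome 11) separated the lines. In the vector line it was detected on 0 of 3 vehicle arrays, with a raw signal of 106.8 ± 5.38 (SD, n = 3), and on 0 of 3 R5020 arrays. With vehicle, its normalized log2 signal was 8.98 ± 0.12 (SD, n = 3) in the WTPR line and 10.80 ± 0.06 in the mCDPR line. These were at least 15.3-fold and at least 54-fold above the vector line. With vehicle, PGR was 1.82 (SE 0.07) higher in the mCDPR than in the WTPR line (adjusted p = 8.87e-11). With R5020 it fell by 0.85 in the WTPR line and fell by 2.27 in the mCDPR line. The labels do not say whether the constructs hold the sequence this probe reads, so the level of the constructs' transcripts is not separated here from that of the cells' own gene.

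In the vector line, R5020 changed 0 of 16210 genes past the threshold in limma, against 1814 genes with an unadjusted p under 0.05. Other settings called 11, 10 or 21 genes. FKBP5, a cochaperone of steroid receptors and a standard progestin target, stood at 8.85 ± 0.10 (log2, SD, n = 3) with vehicle and 8.83 ± 0.04 with R5020. Of the 41 measured progestin and glucocorticoid target genes, 0 passed over all genes and 1 was higher when adjusted over the list alone. None of the 22 gene lists passed in this line, and the progestin list had an adjusted p of 0.559. The hypoxia and glycolysis list was called lower by camera without vehicle replicate 1 or R5020 replicate 1 of the vector line (adjusted p = 0.0108 and 0.00475). With all arrays its adjusted p was 0.185. Without vehicle replicate 1, all remaining vehicle arrays of this line had names ending in _2, and no R5020 array of it did. These vehicle arrays also differed from the R5020 arrays in their position in the deposited table. That setting therefore cannot tell R5020 from the suffix or the position. Between vehicle and R5020 arrays, 2595 genes (16%) had groups that did not overlap, where chance gives 10%. Over the 1841 genes that changed in both PR-B lines, the median vector response in the WTPR direction was 0.005, with quartiles of -0.08 and 0.09.

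**Figure D1:**
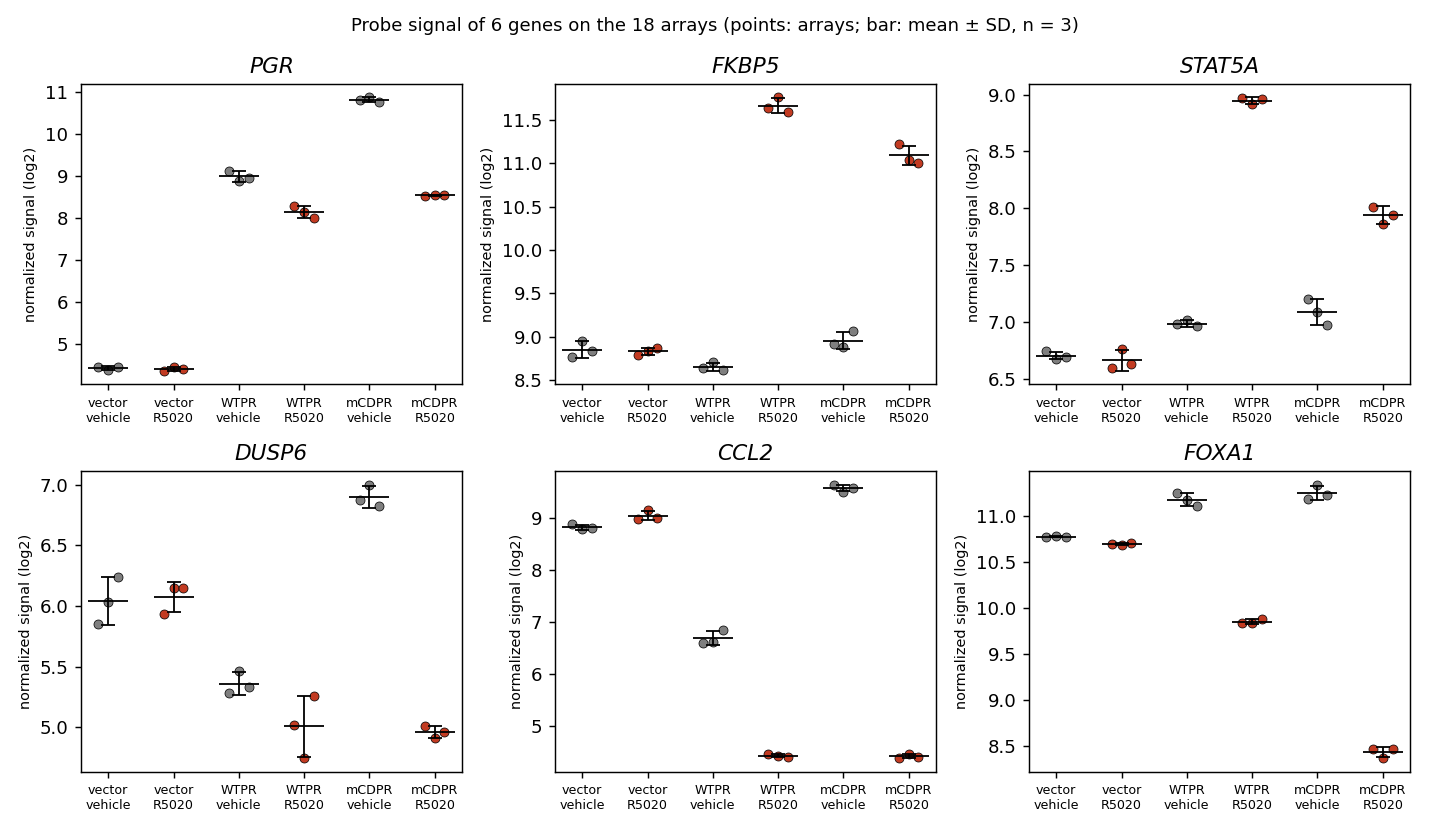
Normalized log2 probe signal of 6 genes on each of the 18 arrays, by line and treatment; points are arrays, grey for vehicle and red for R5020, and bars give the mean ± SD of 3 arrays. PGR is at background in the vector line and highest in the mCDPR line with vehicle (10.80), FKBP5 and STAT5A rise with R5020 in the PR-B lines alone, and FOXA1 falls furthest in the mCDPR line. DUSP6 and CCL2 start highest in the mCDPR line and lie near or at background with R5020 in both PR-B lines, so the sizes of their falls are not ranked.

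In the WTPR line, R5020 raised a set of known progestin and glucocorticoid targets within 6 hours. FKBP5 (chromosome 6) rose by 3.01 (SE 0.07), SGK1, a kinase of sodium and survival signalling, by 3.10 (SE 0.08), NDRG1, a stress and hypoxia gene, by 2.99 (SE 0.08) and TIPARP, an ADP-ribosyltransferase, by 2.99 (SE 0.07). Of the 41 measured genes of this list, 26 rose, 5 fell and 10 did not pass, and the counts adjusted over the list alone were also 26 and 5 (camera adjusted p = 2.46e-16, and 1.62e-05 with an estimated correlation). PHACTR3 (chromosome 20), which binds actin and protein phosphatase 1, rose at least 25-fold. ADGRA2, an adhesion receptor, rose at least 13.7-fold and ARMC12 by 4.46 (SE 0.18) with 2 of 3 vehicle arrays above background. RHOU, a small GTPase, rose by 3.50, KCNG1, a potassium channel subunit, by 3.22, HES2, a transcriptional repressor, by 3.10, and ZNF812P by 3.21 with 1 of 3 vehicle arrays above background. ACOT6 rose at least 8.07-fold and the neurotrophin gene BDNF at least 7.5-fold. Large falls were those of VAV3, a guanine nucleotide exchange factor (fell by 2.79, SE 0.10), the ephrin EFNB2 (fell by 2.02), the transcription factor SOX2 (fell by 2.02), SCHIP1 (fell by 1.93), ENC1 (fell by 1.88) and ID2, an inhibitor of helix-loop-helix factors (fell by 1.84). The chemokine genes CCL2 and CCL20 fell at least 3.17-fold and at least 3.78-fold, SLC7A2 at least 3.5-fold and DLG2 at least 3.17-fold.

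The genes the study title points to changed in the WTPR line as follows. STAT5A (chromosome 17), a transcription factor activated by JAK kinases, rose by 1.96 (SE 0.07, adjusted p = 1.28e-11), and STAT5B by 0.81 (SE 0.13, adjusted p = 2.5e-04). PRLR, the prolactin receptor upstream of JAK2, rose by 1.00 (SE 0.06) and SOCS2, a feedback inhibitor of this pathway, by 1.14 (SE 0.21), with 2 of 3 vehicle arrays above background. Of 36 JAK/STAT components, 6 rose, 5 fell and 25 did not pass; adjusted over the list alone, 7 rose and 5 fell. The list had a median of -0.06 and a mean of 0.07, and camera, pointing up, did not call it (adjusted p = 0.786). Of 15 STAT5 target genes, 5 rose and 3 fell (adjusted over the list alone, 6 and 3, camera adjusted p = 0.349), with CCND1, the cyclin that drives entry into S phase, up by 1.02 (SE 0.06) and BCL6, a transcriptional repressor, up by 1.03 (SE 0.07). DUSP6 (chromosome 12) changed by -0.35 (SE 0.12, adjusted p = 0.0584) and was above background on 2 of 3 R5020 arrays. WNT1, which encodes a secreted ligand, was above background on 0 of 3 vehicle and 2 of 3 R5020 arrays of this line, and was higher by at least 1.02-fold (adjusted p = 0.00248). JAK2 was detected on 1 of 18 arrays, and the 3 probes of NR3C1, the glucocorticoid receptor, on 0, 0 and 2, so neither was tested.

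Several other gene groups moved in the WTPR line. Of 62 cell-cycle genes 16 rose and 2 fell (adjusted over the list alone, 19 and 2, camera adjusted p = 5.9e-05, and 0.00175 with an estimated correlation). Among them were the G1/S cyclin CCNE2 (up by 0.85, SE 0.07), the phosphatase CDC25A (0.60, SE 0.06) and UHRF1 (0.58, SE 0.07), which maintains DNA methylation. Luminal epithelial markers went the other way, with 10 of 20 lower and 1 higher (over the list alone, 10 and 2, adjusted p = 3.4e-07, and 6.41e-04 with an estimated correlation). FOXA1, a pioneer factor for steroid receptors, fell by 1.32 (SE 0.06), and ELF3 (-1.36, SE 0.07), SPDEF (-0.85, SE 0.07) and XBP1 (-0.67, SE 0.05) fell too. Nuclear receptors and cofactors fell in 12 of 21 cases and rose in 2 (over the list alone, 13 and 3, adjusted p = 0.0104 with an estimated correlation), although NCOA1, a coactivator, rose by 1.09 (SE 0.07) and VDR, the vitamin D receptor, by 1.04 (SE 0.08). Of 24 apoptosis regulators 11 rose and 2 fell (over the list alone, 11 and 2, adjusted p = 0.0156 with an estimated correlation). BIRC3, an inhibitor of caspase activation, rose by 1.90 (SE 0.08), TNFRSF10B, a death receptor, by 0.71 (SE 0.06) and BMF, a promoter of apoptosis, by 1.06 (SE 0.13).

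The remaining lists were called under the preset correlation alone or not at all in the WTPR line. Hypoxia and glycolysis genes rose in 10 of 30 cases and fell in 1 (adjusted over the list alone, 11 and 1, adjusted p = 0.0693 with an estimated correlation). Metallothioneins rose in 3 of 6 cases, MT1X by 0.64 (SE 0.09) and MT2A by 0.63 (SE 0.10), with 4 higher over the list alone (adjusted p = 0.13 with an estimated correlation). Interferon-stimulated genes had 12 of 52 lower and 3 higher (over the list alone, 14 and 3, adjusted p = 0.567 with an estimated correlation), with GBP2 down (-0.75, SE 0.12) and TRIM22 up at least 2.66-fold. Without vehicle replicate 3 or R5020 replicate 1 of the WTPR line that list was not called (adjusted p = 0.331 and 0.209). Adhesion and junction genes had 10 of 35 lower and 6 higher (over the list alone, 11 and 6, adjusted p = 0.181 with an estimated correlation), with CLDN1 at -0.99 (SE 0.07). The lists not called by camera were ERK feedback genes and targets (7 higher and 6 lower of 33, and 8 and 8 over the list alone), the WNT pathway (4 and 6 of 29; 5 and 8), estrogen response (7 and 9 of 31; 7 and 11), sterol and fatty acid synthesis (8 and 3 of 33; 8 and 3), the endoplasmic reticulum (ER) stress response (7 and 3 of 26; 9 and 5), heat shock (1 and 4 of 23; 1 and 4), and growth factor receptors and ligands (4 and 7 of 29; 4 and 7). Markers of other cell types were not called either: basal (6 and 3 of 18; 8 and 4), stromal (1 and 1 of 14; 1 and 1), endothelial (0 and 1 of 6; 1 and 1) and leukocyte (0 and 0 of 10; 0 and 0). In the growth factor list, EGFR rose by 1.40 (SE 0.10) and GRB10, an adaptor of the insulin receptor, by 2.18 (SE 0.06).

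In all, 2502 genes changed with R5020 in the WTPR line, 1209 higher and 1293 lower, and 555 and 345 of them by at least 1.5-fold. Under median scaling of the arrays the split was 903 higher and 1854 lower. Groups did not overlap for 5071 genes (31.3%), where chance gives 10%. Set against the response of the vector line, 1699 genes differed, 856 higher and 843 lower. These included STAT5A at 2.00 (SE 0.09), KCNG1 at 3.23 (SE 0.09), HSD11B2, which inactivates cortisol, at 3.29 (SE 0.18), the death ligand TNFSF10 at -1.94 (SE 0.25; 1 of 3 WTPR arrays above background with R5020) and NFKBIZ at -1.81 (SE 0.14).

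In the mCDPR line R5020 changed more genes, and many of the large changes were in the same genes. PHACTR3 rose at least 75.6-fold, ADGRA2 at least 32.7-fold, ACOT6 at least 12.6-fold, ARMC12 by 3.54 (SE 0.18) and TIPARP by 3.19 (SE 0.07). The hair-root keratin genes KRT73 and KRT72 (chromosome 12) rose at least 15-fold and at least 7.28-fold, TRAF5, an adaptor of tumour necrosis factor receptors, at least 7.8-fold, the cytokine receptor IL20RA by 3.40 (SE 0.11), and NPTX1, a neuronal pentraxin, by 3.52 (SE 0.14) with 1 of 3 vehicle arrays above background. CCL2 fell at least 23.7-fold, and CCL20 fell by 3.87 (SE 0.10). Other large falls were VAV3 (-3.51, SE 0.10), SOX2 (-2.95, SE 0.08), the cadherin CDH10 (-2.87, SE 0.06), TFAP2B (-2.86, SE 0.10), SPRY1, a feedback inhibitor of ERK signalling (-2.86, SE 0.07), and BCL3 (-2.79, SE 0.07; 2 of 3 R5020 arrays above background). Of the 41 progestin and glucocorticoid targets 23 rose and 5 fell (over the list alone, 24 and 7, camera adjusted p = 1.14e-07, and 5.27e-04 with an estimated correlation). FKBP5 rose by 2.13 (SE 0.07), CEBPD, a transcription factor of growth arrest, by 1.65 (SE 0.06) and SGK1 by 1.21 (SE 0.08), while ELF5, a transcription factor of the alveolar lineage, fell by 2.14 (SE 0.06).

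Luminal markers fell in 15 of 20 cases and rose in 0 in the mCDPR line (over the list alone, 16 and 0, camera adjusted p = 3.89e-10, and 2.31e-04 with an estimated correlation). FOXA1 fell by 2.81 (SE 0.06), ELF3 changed by -3.09 (SE 0.07), GATA3, a factor that specifies luminal cells, by -1.83 (SE 0.06) and XBP1 by -1.78 (SE 0.05). Nuclear receptors and cofactors fell in 12 of 21 cases and rose in 3 (over the list alone, 13 and 3, adjusted p = 0.00814 with an estimated correlation), VDR rising by 1.99 (SE 0.08). Of 52 interferon-stimulated genes 42 fell and 1 rose (over the list alone, 46 and 1, adjusted p = 3.08e-15, but adjusted p = 0.176 with an estimated correlation). IFIT2, which binds viral RNA, changed by -2.73 (SE 0.19), the antiviral gene OASL by -1.89 (SE 0.15) and the chemokine gene CXCL10 by -1.36 (SE 0.10), and TRIM22 rose by 1.32 (SE 0.10) with 1 of 3 vehicle arrays above background. ERK feedback genes and targets fell in 15 of 33 cases and rose in 5 (over the list alone, 17 and 5, adjusted p = 0.00924, and 0.046 with an estimated correlation). Besides SPRY1, the chemokine gene CXCL8 fell at least 3.86-fold and PHLDA1 fell by 1.53 (SE 0.09). DUSP6 fell by 1.94 (SE 0.12, adjusted p = 4.2e-09), from a raw signal of 221.5 ± 5.64 (SD, n = 3) to 128.4 ± 1.26, with 1 of 3 R5020 arrays above background.

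STAT5A rose by 0.85 (SE 0.07, adjusted p = 6.67e-08) in the mCDPR line, STAT5B by 0.41 (SE 0.13, adjusted p = 0.0227) and PRLR by 0.68 (SE 0.06). Of 36 JAK/STAT components 6 rose and 12 fell (over the list alone, 7 and 12, camera adjusted p = 0.936, median 0.006, mean -0.05), and of 15 STAT5 targets 4 rose and 3 fell (over the list alone, 4 and 3, camera adjusted p = 0.952). Among these, the kinase gene PIM2 rose by 2.57 (SE 0.08), MYC by 1.49 (SE 0.08) and CCND1 by 0.89 (SE 0.06). The WNT1 probe was above background on 0 of 3 vehicle and 1 of 3 R5020 arrays, too dim for a fold, and its rise was called (adjusted p = 0.00847). Cell-cycle genes rose in 13 and fell in 13 of 62 cases (over the list alone, 14 and 13, adjusted p = 0.68). Hypoxia and glycolysis genes rose in 14 of 30 cases and fell in 1 (over the list alone, 14 and 3, adjusted p = 0.0568 with an estimated correlation), and PFKFB3, an activator of glycolysis, rose by 2.14 (SE 0.07). Metallothioneins rose in 4 of 6 cases, MT1F by 1.66 (SE 0.12), with 4 over the list alone (adjusted p = 0.176 with an estimated correlation). Adhesion genes fell in 15 of 35 cases and rose in 5 (over the list alone, 16 and 6, adjusted p = 0.176 with an estimated correlation), with TJP3 at -1.31 (SE 0.06). The other lists were not called by camera: the WNT pathway (7 higher and 8 lower of 29, and 8 and 8 over the list alone), estrogen response (9 and 9 of 31; 11 and 10), sterol synthesis (10 and 6 of 33; 10 and 10), ER stress (7 and 8 of 26; 9 and 9), heat shock (3 and 7 of 23; 5 and 7), growth factor receptors (7 and 7 of 29; 7 and 9), apoptosis (8 and 6 of 24; 8 and 7), and basal (5 and 9 of 18; 5 and 9), stromal (1 and 3 of 14; 1 and 3), endothelial (2 and 2 of 6; 2 and 2) and leukocyte markers (0 and 2 of 10; 0 and 2).

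R5020 changed 4837 genes in the mCDPR line, 2334 higher and 2503 lower, with 1040 and 755 of them by at least 1.5-fold. Groups did not overlap for 6765 genes (41.7%), where chance gives 10%. Set against the vector line's response, 3500 genes differed, 1766 higher and 1734 lower, and under median scaling the split was 1924 and 896. These included STAT5A at 0.90 (SE 0.09), DUSP6 at -1.98 (SE 0.17; 1 of 3 mCDPR arrays above background with R5020), the transcription factor gene FOXO4 at 3.11 (SE 0.12), TNFSF10 at -2.93 (SE 0.25; 2 of 3 mCDPR arrays above background with R5020) and IFIT2 at -2.85 (SE 0.27).

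**Figure D2:**
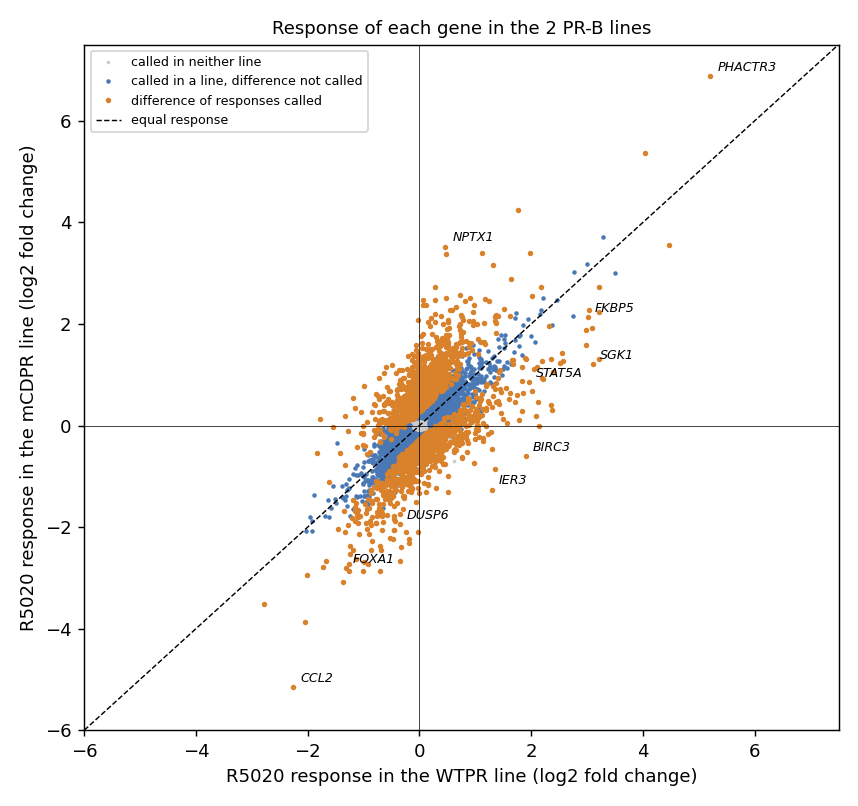
Log2 fold change with R5020 in the WTPR line (x axis) against that in the mCDPR line (y axis) for 16210 genes; grey genes were called in neither line, blue genes in at least 1 line, and orange genes in the difference of responses, with a dashed line of equal response. The responses rise together (Pearson r = 0.606 across genes), with an orthogonal slope through the origin of 1.35 for genes changed in both, steeper than the dashed line. FOXA1 lies below that line, as do the fitted values of CCL2 and DUSP6, which near or reach background with R5020, and BIRC3 and IER3 rise in WTPR and fall in mCDPR.

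The lines' responses overlapped widely and differed in size. In both lines 823 genes rose, where independent lists would share 174.1, and 913 fell, against 199.7. Another 105 genes changed in opposite directions. Across all genes, which are not independent replicates, the responses had Pearson r = 0.606 and Spearman rho = 0.429. Among the 1841 genes changed in both, the median size of the response was 0.50 in WTPR and 0.65 in mCDPR. An orthogonal fit through the origin, which treats both lines alike, gave a slope of 1.35 for mCDPR against WTPR. It is not the slope of an ordinary regression. A change called in one line and not the other does not show a difference, and the test of the difference itself follows.

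The response differed between the WTPR and mCDPR lines for 2011 genes, in the WTPR minus mCDPR direction 846 positive and 1165 negative; median scaling gave 469 and 1573. STAT5A responded more in WTPR, by 1.11 (SE 0.09, adjusted p = 1.04e-06). The STAT5B difference was 0.40 (SE 0.18, adjusted p = 0.185) and that of WNT1 did not pass (adjusted p = 0.708). For DUSP6 the fitted difference was 1.59 (SE 0.17, adjusted p = 9.59e-06), but background limits it. With vehicle DUSP6 stood at 5.36 in WTPR and 6.90 in mCDPR (log2, n = 3), a difference of 1.54 (SE 0.12). With R5020 it stood at 5.01 and 4.96, where the lowest detected signal per array was 4.98 to 5.06, so the fall in WTPR had little room and its size is not compared with that in mCDPR. PGR likewise differed by 1.42 (SE 0.11). SGK1 rose more in WTPR, by 1.89 (SE 0.11), and SOCS2 by 1.40 (SE 0.30), while PIM2 (-1.84, SE 0.11) rose more in mCDPR. The MYC difference of -1.55 (SE 0.11) goes with its level with vehicle, which differed by -1.33 between mCDPR and WTPR (adjusted p = 7.84e-09), against 0.22 with R5020. Some genes moved in opposite directions: IER3, an early response gene, changed by 1.30 in WTPR and -1.26 in mCDPR (difference 2.56, SE 0.13), BIRC3 by 1.90 and -0.60 (2.50, SE 0.11; 1.88 higher in mCDPR with vehicle), RUNX1 by 1.36 and -0.86 (2.22, SE 0.36; 2 of 3 mCDPR R5020 arrays above background) and IRF1 by 0.61 and -0.49 (1.10, SE 0.12).

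Genes that responded mainly in mCDPR included NPTX1 (difference -3.06, SE 0.20; 1 of 3 vehicle arrays above background in each line), the tubulin-binding STMN3 (-2.46, SE 0.10), and, falling there, ID3 (2.32, SE 0.17; 1 of 3 mCDPR R5020 arrays above background) and CDH10 (2.15, SE 0.09). TNFRSF19 fell there too (2.12, SE 0.15), but it was 4.13 (SE 0.11) higher in mCDPR with vehicle, and its level of 5.64 in WTPR left little room for a fall. KRT72, KRT73, TRAF5, ELFN2, EPB41L3, CYP26A1, KRT17P5, OTOS, FUT2 and LOC400707 differed too, but were not above background in at least 1 of the groups compared, so no size is given for them here. ANKRD24 rose by 2.14 in WTPR, with 1 of 3 vehicle arrays above background, and its response in mCDPR was -0.002 (difference 2.15, SE 0.19). CCL2 reached background with R5020 in both lines, and with vehicle it stood at 6.69 in WTPR and 9.58 in mCDPR (log2, n = 3). Of the 2011 genes, 439 changed the same way in both lines and more in mCDPR, 96 the same way and more in WTPR, 105 in opposite ways, 1084 in mCDPR and not WTPR, 231 in WTPR and not mCDPR, and 56 in neither. The lines differed with vehicle and not with R5020 for 456 of these genes, with R5020 and not vehicle for 932, under both for 568 and under neither for 55.

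Gene groups differed as well. Of the progestin targets 11 responded more positively in WTPR and 6 less (over the list alone, 13 and 6, camera adjusted p = 0.0131, and 0.0462 with an estimated correlation). ERK feedback genes and targets did so in 12 and 2 of 33 cases (over the list alone, 14 and 2, adjusted p = 1.08e-05, and 0.00319 with an estimated correlation). SPRY1 differed by 1.60 (SE 0.10), being 1.55 higher in mCDPR with vehicle, and SPRED1 by 1.15 (SE 0.09). Luminal markers fell less in WTPR, in 7 of 20 cases against 1 (over the list alone, 9 and 1, adjusted p = 0.00271 with an estimated correlation). FOXA1 differed by 1.49 (SE 0.08) and GATA3 by 1.38 (SE 0.09). The means of the progestin, ERK and luminal lists were already lower in WTPR than in mCDPR with vehicle. Part of each difference may therefore lie in the starting level. Nuclear receptors (7 and 2 of 21, over the list alone, 7 and 3) and cell-cycle genes (5 and 3 of 62, over the list alone, 5 and 3) each had adjusted p = 0.0462 with an estimated correlation. Neither was called under median scaling (adjusted p = 0.0584 and 0.33), nor nuclear receptors over every kept probe (0.07). Interferon-stimulated genes were more positive in WTPR in 22 of 52 cases and less in 0 (over the list alone, 32 and 0, adjusted p = 0.21 with an estimated correlation), and basal markers in 6 and 1 of 18 (over the list alone, 9 and 1, adjusted p = 0.0961 with an estimated correlation). JAK/STAT components (5 and 3 of 36, over the list alone, 6 and 4, adjusted p = 0.191), STAT5 targets (4 and 3 of 15, over the list alone, 4 and 3, adjusted p = 0.453) and the WNT pathway (3 and 4 of 29, over the list alone, 5 and 4, adjusted p = 0.427) were not called, nor were the other 12 lists.

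**Figure D3:**
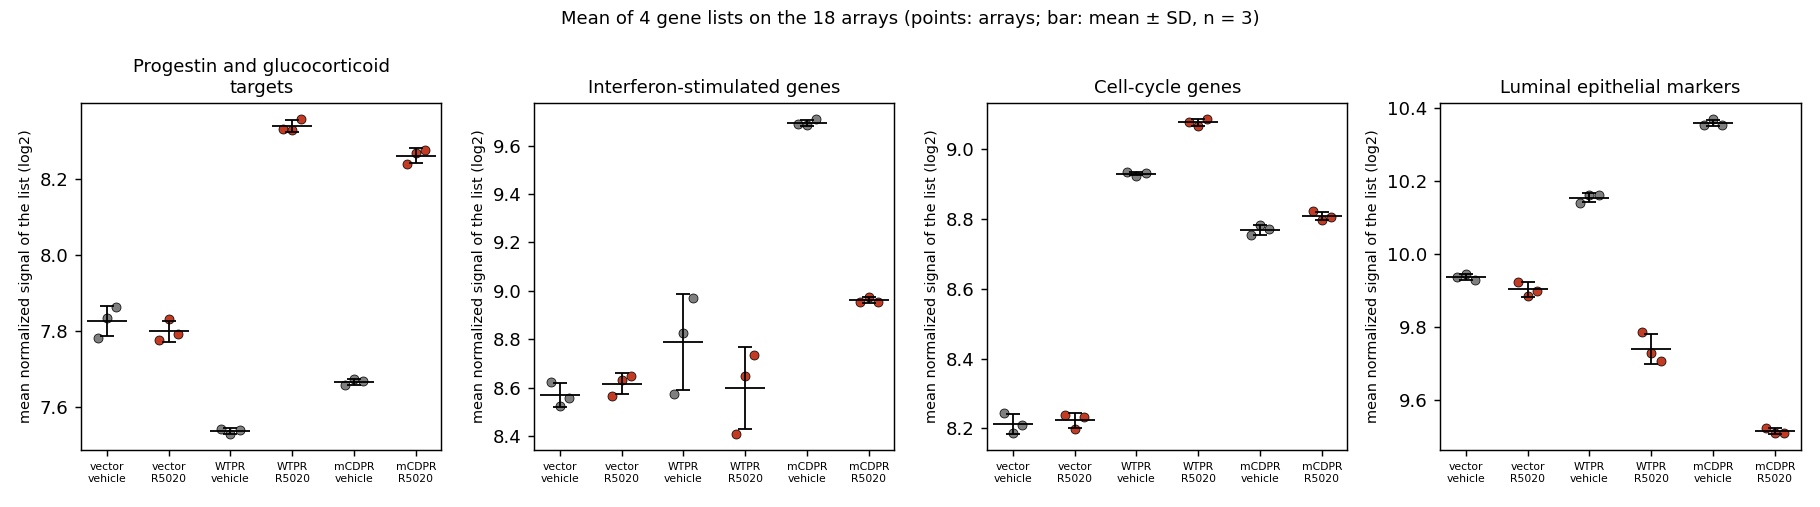
Mean normalized log2 signal of 4 gene lists on each of the 18 arrays, by line and treatment; points are arrays, grey for vehicle and red for R5020, and bars give the mean ± SD of 3 arrays. Interferon-stimulated genes average 9.69 in the mCDPR line with vehicle and 8.96 with R5020, cell-cycle genes are lowest in the vector line (8.21 with vehicle), and luminal markers fall with R5020 in both PR-B lines.

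The lines already differed with vehicle alone. In the WTPR line against the vector line, CD36, a fatty acid receptor (chromosome 7), was 3.62 (SE 0.18) higher, with 2 of 3 vector arrays above background, the cytidine deaminase gene APOBEC3B 2.79 (SE 0.11), TM4SF1 2.74 (SE 0.12), the small heat shock gene CRYAB 2.52 (SE 0.15) and NCAM2 2.42 (SE 0.07). CDSN, a protein of cornified skin, changed by -4.87 (SE 0.09; 2 of 3 WTPR arrays above background), SERPINA3, a protease inhibitor, by -3.33 (SE 0.06) and CYP1A1, a target of the aryl hydrocarbon receptor, by -3.13 (SE 0.12). LDHB, a lactate dehydrogenase subunit, was at least 13.6-fold lower. Cell-cycle genes were higher in 52 of 62 cases and lower in 1 (over the list alone, 52 and 1, camera adjusted p = 2.95e-07 with an estimated correlation). CCNA2 was higher by 1.18 (SE 0.06), GINS2 by 1.18 (SE 0.05) and AURKB by 1.13 (SE 0.06). Progestin targets were lower in 18 and higher in 4 of 41 cases (over the list alone, 21 and 6, adjusted p = 0.00573 with an estimated correlation), with CDKN1A at -1.28 (SE 0.07), although SGK1 was 1.78 (SE 0.08) higher. ERK feedback genes and targets were lower in 14 and higher in 2 of 33 cases (over the list alone, 16 and 3, adjusted p = 0.0371 with an estimated correlation), DUSP6 by -0.68 (SE 0.12). Hypoxia genes (15 lower and 6 higher of 30, over the list alone, 15 and 6), sterol synthesis genes (16 higher and 4 lower of 33, over the list alone, 18 and 5), luminal markers (9 higher and 5 lower of 20, over the list alone, 10 and 5) and stromal markers (5 lower and 1 higher of 14, over the list alone, 6 and 1) were called under the preset correlation. With an estimated correlation their adjusted p-values were 0.0773, 0.0726, 0.0773 and 0.0773. Interferon-stimulated genes were higher in 25 and lower in 10 cases (over the list alone, 27 and 11, adjusted p = 0.601 with an estimated correlation, and 0.146 under the preset one without WTPR vehicle replicate 3).

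In the mCDPR line against the vector line, butyrylcholinesterase (BCHE, chromosome 3) was at least 31.8-fold higher, EPSTI1, an interferon-stimulated gene, at least 12.4-fold, and ARHGDIB and RAC2, both of GTPase signalling, at least 10.6-fold and at least 9.74-fold. FAM133A was at least 8.38-fold higher and the cancer-testis antigen genes XAGE1A and MAGEA10 were 3.75 (SE 0.09) and 5.09 (SE 0.23) higher; 1 of 3 vector arrays measured MAGEA10. LDHB was at least 13.3-fold lower, GPNMB at least 3.54-fold lower, PGLYRP2 changed by -3.56 (SE 0.10) and MYC by -1.76 (SE 0.08). Interferon-stimulated genes were higher in 42 of 52 cases and lower in 0 (over the list alone, 43 and 0, adjusted p = 0.0678 with an estimated correlation). ISG15 was higher by 2.11 (SE 0.13) and IFITM3 by 2.54 (SE 0.15). Cell-cycle genes were higher in 49 and lower in 1 (over the list alone, 51 and 1, adjusted p = 8.01e-07 with an estimated correlation), UBE2C by 1.03 (SE 0.06). Sterol synthesis genes (17 higher and 4 lower of 33, over the list alone, 18 and 4) and luminal markers (9 higher and 2 lower of 20, over the list alone, 9 and 3) each had adjusted p = 0.00426 with an estimated correlation, with TFF3, a luminal marker, up by 2.19 (SE 0.10). Heat shock genes were lower in 12 and higher in 2 of 23 cases, although CRYAB was 3.24 (SE 0.15) higher. Over the list alone the counts were 13 and 3 (camera adjusted p = 0.0284 with an estimated correlation). The list was not called without the 4 arrays whose name ends in _2. That setting was chosen after seeing the data and keeps only vehicle replicate 1 of the vector line. Hypoxia (12 lower and 3 higher of 30, over the list alone, 13 and 3) and estrogen response genes (12 lower and 4 higher of 31, over the list alone, 12 and 4) had adjusted p-values of 0.129 and 0.0678 with an estimated correlation.

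Directly compared with vehicle, the mCDPR line stood above the WTPR line in BCHE (at least 33.4-fold), XAGE1A by 4.53 (SE 0.09), CDSN by 4.52 (SE 0.09; 2 of 3 WTPR arrays above background), TNFRSF19 by 4.13 (SE 0.11), SERPINA3 by 3.72 (SE 0.06) and EPSTI1 by 3.66 (SE 0.09; 2 of 3 WTPR arrays above background). It stood below in TM4SF1 (-3.57, SE 0.12), the potassium channel gene KCNK2 (-3.14, SE 0.13), smooth muscle actin ACTA2 (-2.88, SE 0.06), CD36 (-2.82, SE 0.18) and MGP, an inhibitor of calcification (-2.20, SE 0.07). Interferon-stimulated genes were higher in 40 of 52 cases and lower in 0 (over the list alone, 46 and 0, adjusted p = 0.0794 with an estimated correlation). IFI27 was higher by 3.16 (SE 0.14) and CXCL10 by 2.51 (SE 0.10). Cell-cycle genes were lower in 27 and higher in 5 (over the list alone, 29 and 6, adjusted p = 0.0132 with an estimated correlation). ER stress genes (10 higher and 4 lower of 26, over the list alone, 12 and 4) and luminal markers (9 and 2 of 20, over the list alone, 10 and 2) each had adjusted p = 0.0412 with an estimated correlation, but neither was called under median scaling (adjusted p = 0.115 and 0.105). ERK genes (9 and 3 of 33, over the list alone, 9 and 3) and leukocyte markers (3 and 0 of 10, over the list alone, 3 and 0) had 0.0682 and 0.0794, CD74 being 1.42 (SE 0.11; 1 of 3 WTPR arrays above background) and HLA-DRA 1.15 (SE 0.09) higher. STAT5A differed by 0.10 (SE 0.07, adjusted p = 0.307).

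With vehicle, 4919 genes differed between WTPR and vector (2605 higher, 2314 lower), 4624 between mCDPR and vector (2268 and 2356) and 4449 between mCDPR and WTPR (2051 and 2398). Under median scaling these splits were 5761 and 1031, 2761 and 1244, and 1178 and 4289. That scaling set the median of all genes at 0.18 in WTPR against vector and -0.13 in mCDPR against WTPR, so changes there are relative to those shifts, and the lists named above kept their direction against all genes under it. Groups did not overlap for 6708, 6473 and 6515 genes (41.4%, 39.9% and 40.2%), where chance gives 10%. The lists against the shared vector arrays had 1301 higher and 1082 lower genes in common, where independent lists would share 364.5 and 336.3. The fold changes correlated at r = 0.544 across genes, where simulated lines with no effect gave 0.501 from the shared arrays alone, and their covariance was 0.0774 against a simulated 0.0101. The 3 control arrays cannot be split with at least a pair on each side, so part of this overlap may come from the shared arrays.

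With R5020, 5305 genes differed between mCDPR and WTPR, 2531 higher and 2774 lower. MAGEA10 was 4.80 (SE 0.23) higher in mCDPR, with 2 of 3 WTPR arrays above background, BCHE at least 18.7-fold, the lipid carrier gene APOE at least 6.33-fold, EPB41L3 at least 7.83-fold and NPTX1 3.06 (SE 0.14; 2 of 3 WTPR arrays). Lower in mCDPR were ACTA2 (-3.16, SE 0.06), ARID5B (-2.56, SE 0.07), ID3 (-2.48, SE 0.12; 1 of 3 mCDPR arrays above background), STAT5A (-1.01, SE 0.07) and STAT5B (-0.42, SE 0.13, adjusted p = 0.0177). Cell-cycle genes were lower in mCDPR in 35 of 62 cases and higher in 3 (over the list alone, 37 and 3, camera adjusted p = 8.98e-04 with an estimated correlation), CCNE2 by -0.86 (SE 0.07) and HMMR by -0.98 (SE 0.10). Interferon-stimulated genes were higher in 17 and lower in 6 (over the list alone, 17 and 6, adjusted p = 0.713 with an estimated correlation, and 0.249 under the preset one without WTPR R5020 replicate 1). No other list was called. For PKP1, another probe was called in the direction opposite to the tested one. Groups did not overlap for 7301 genes (45%), where chance gives 10%.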

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

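The splits of the arrays were planned; the tests that weigh the larger response in mCDPR and the interferon genes were chosen after the result was seen.

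A different response to R5020 in different lines, by a test of the difference itself, drew attention to 2011 genes for WTPR against mCDPR, 1699 for WTPR against vector and 3500 for mCDPR against vector. In 6 of 100 splits of the arrays within the lines, as many genes as the real 2011 differed between WTPR and mCDPR, the highest other count being 2958. All 5 such splits other than the real one kept the mCDPR arrays of each treatment together and mixed those of WTPR, so they leave the mCDPR response in place and are not chance groupings; the 80 splits that mixed both lines called at most 0 genes. The share of splits therefore does not decide whether chance gives such a count. For WTPR and mCDPR against vector, 1 of 100 splits (the real one) gave as many, with 1518 and 3297 as the highest others. The high counts there too come from splits that kept the WTPR or mCDPR arrays of each treatment together and mixed those of vector. The splits mix treatments within lines, so a small share speaks against no response in either of the lines compared. It does not decide whether the difference of their responses comes from chance. The 84 and 81 splits that mixed both lines called at most 2 genes. In a split that mixes treatments, a real response widens the spread within the mixed groups. The low counts of such splits therefore do not show what chance alone gives.

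For comparisons of 3 against 3 arrays, the 10 possible splits are too few for a share under 0.05. The real counts and highest others were 0 and 1 for R5020 in the vector line (10 of 10 splits with as many), 2502 and 1 in WTPR, 4837 and 1 in mCDPR, 4919 and 0 for WTPR against vector with vehicle, 4624 and 2 for mCDPR against vector, 4449 and 0 for mCDPR against WTPR, and 5305 and 0 for mCDPR against WTPR with R5020. In each of these but the first, 1 split, the real one, gave as many genes. The other splits mix the groups compared, so a real difference widens their spread, and their low counts do not show what chance alone gives.

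The lists whose response differed between WTPR and mCDPR in all 33 settings had mean differences (WTPR minus mCDPR) of 0.208 for progestin and glucocorticoid targets, 0.437 for ERK feedback genes and targets and 0.431 for luminal markers. Interferon-stimulated genes (0.541) and basal markers (0.307) were called with the preset correlation between genes but not with an estimated one (adjusted p = 0.21 and 0.0961). Nuclear receptors (0.241) and the cell cycle (0.107) were not called under median scaling (adjusted p = 0.0584 and 0.33), where the cell-cycle mean was -0.014. With vehicle, list means in WTPR and mCDPR were already 7.54 and 7.67 (progestin), 6.29 and 6.51 (ERK) and 10.15 and 10.36 (luminal). Between these lines with R5020, none of these lists was called in any of the 33 settings. Part of each difference in response may therefore lie in the starting level. The gene differences were, for those more positive in WTPR, PGR 1.42, STAT5A 1.11, IER3 2.56, BIRC3 2.50 and CDH10 2.15, and, more positive in mCDPR, STMN3 -2.46. For ID3 2.32, RUNX1 2.22, ANKRD24 2.15 and NPTX1 -3.06, some arrays of a group compared were not above background. For DUSP6 (1.59) and TNFRSF19 (2.12), WTPR levels with vehicle near background left little room for a fall, so the fitted difference is no measure of a smaller response. For genes not above background in at least 1 of the groups the fitted difference is no bound: CCL2 2.90, FUT2 2.07, LOC400707 2.05, KRT72 -2.90, KRT73 -2.49, ELFN2 -2.41, EPB41L3 -2.30, TRAF5 -2.28, CYP26A1 -2.26, KRT17P5 -2.19 and OTOS -2.09. Probes without a gene symbol, outside the tested genes, also responded: 66 of 1818 in WTPR and 120 in mCDPR, against 0 in the vector line. These shares (3.63% and 6.6%) were lower than those of probes with a symbol (13.23% and 26.77%, and 0% in the vector line).

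Among the 1841 genes changed by R5020 in both lines, the median size of the response was larger in mCDPR (0.65) than in WTPR (0.50). The difference itself was called for a part of them. With a shared direction, 439 changed more in mCDPR and 96 more in WTPR. The pooled residual SD was 0.1694 with vehicle and 0.1688 with R5020 in mCDPR, against 0.1631 and 0.1635 in WTPR. This argues against less spread between the mCDPR arrays as the cause. The lowest orthogonal slope of mCDPR against WTPR responses with any array left out was 1.3069, but leaving out 1 array hardly changes the spread and does not test that cause. The lowest slope under other background corrections, scalings and filters was 1.3134, which argues against normalization. Of the genes with a shared direction and a different size, 17.9% responded more in WTPR, against a limit of 5% set after the result was seen. The 95% interval (14.8% to 21.5%) treats genes as independent, which they are not. These values argue against one gain factor for every gene but do not exclude it. The PGR signal was 1.822 higher (log2) in mCDPR with vehicle, and a higher receptor level cannot be told apart from the mutation, with 1 line per construct. The mutation itself is the biological difference in the design and stays open.

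Interferon-stimulated genes stood highest in mCDPR with vehicle and fell there with R5020. The fall of the list mean in mCDPR was 3.68 times the largest SD between arrays of any group, which argues against spread between arrays as its cause. The 46 of 52 members detected on all 18 arrays had a median change of -0.581, which argues against signal near background for these members. It does not exclude it, and since they make up most of the list, their median could hardly differ from that of all members (-0.581). The higher level with vehicle (median 0.637 against WTPR) cannot be told apart from a property of this clone, with 1 line per construct. With the correlation between genes estimated from the data, neither the fall (adjusted p = 0.176) nor the difference with vehicle (adjusted p = 0.0794) was called.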

How the results depend on the processing

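Each of the 10 counts was recomputed under the alternatives; a count is taken as kept when within 1.5 times its value. For the vector line, 0 genes became 11 without background correction, 10 with the authors' values and 21 with a variance trend. The cause was not tested. With a fold minimum of 1.5 the other counts fell, as a second threshold must make them: 900, 1795 and 1105 genes for R5020 in WTPR, in mCDPR and for their difference, 942 and 1898 for WTPR and mCDPR against vector, 1501, 1277 and 1032 for WTPR against vector, mCDPR against vector and mCDPR against WTPR with vehicle, and 1578 with R5020.

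Without the _2 arrays, a setting chosen after seeing the data, there were 1077 and 2288 genes for WTPR and mCDPR against vector in the response, and 3015 and 2433 for these lines against vector with vehicle, with fewer arrays in the fit. A block for the position in the deposited table, also chosen after seeing the data, kept all counts within 1.5 times. Leaving out 1 array at a time gave 0 to 0 genes for R5020 in the vector line, 2047 to 2523 in WTPR, 4245 to 4854 in mCDPR, 1707 to 2027 for their difference, 1370 to 1707 and 3065 to 3491 for WTPR and mCDPR against vector, 4308 to 4931, 3961 to 4629 and 3714 to 4458 for the lines with vehicle in the order above, and 4580 to 5351 with R5020. With the replicate number as a block the counts were 0, 2394, 4736, 1911, 1608, 3358, 4770, 4529, 4301 and 5204 in the order of the ranges above. The numbers are not shown to pair the arrays: for same-numbered arrays of a line, the residuals correlated by 0.0019 on average over 9 pairs, with 0 over 0.1. The block for the chip was not run, since the files used here do not give it.

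Of 220 tests of lists, 62 were called, and 36 with the correlation estimated from the data, which widens the error of a list whose genes move together. Leaving out 1 array gave 56 to 65 and the other settings 55 to 73. No list called in any setting reversed in the direction that camera gives, which is relative to all genes. The mean of a list could still change sign, as the cell-cycle mean for WTPR minus mCDPR did under median scaling. Some lists never called changed camera direction between settings, as estrogen response in mCDPR did (main direction in 24 of 33). The interferon lists in WTPR and mCDPR were called in 30 and 32 of 33 settings. The correlation between responses of WTPR and mCDPR, 0.606 (jackknife SD 0.0224), was 0.648 without background correction, 0.638 with an offset of 50, 0.647 with the authors' values, 0.562 without a filter, 0.659 with the stricter one and 0.583 over every probe; the settings that left out dim probes or compressed their values raised it. Leaving out 1 array gave 0.592 to 0.606.

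Over the named genes, 31879 of the values under an alternative kept a call in the same direction or stayed uncalled, 430 lost the call and 60 gained it. None that was called in the main fit or the alternative reversed direction. Values uncalled in both were not checked for direction. STAT5B in mCDPR was not called in 5 of 33 settings (highest adjusted p 0.128), and the fall of DUSP6 in WTPR was called in 7 of 33. Signal over background limits CCL2, WNT1 and the other genes given as bounds, since a group of theirs has no array above background, and DUSP6, whose R5020 arrays in WTPR and mCDPR were only in part above it.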

Other observations

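The NF-kB tests and those of the arms 12q, 20p, 20q and 21q, with their bounds, were chosen after the results were seen; the test of the spread over arms was planned.

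Genes that differed most between the lines' responses included IER3 and BIRC3, targets of the inflammatory transcription factor NF-kB, and the chemokine gene CCL2 fell to background in both PR-B lines with R5020. A list of 43 measured NF-kB targets was therefore tested. In WTPR minus mCDPR, 18 were more positive and 3 less. Genes on the fixed list of names or among the largest rises and falls of any comparison were then left out. Genes named above only as list members were not. Of the 36 that remained, 12 were more positive and 3 less, and camera with an estimated correlation gave an unadjusted p = 0.00274. The difference may therefore not rest on the genes left out alone. With vehicle 24 genes of the list were higher in mCDPR than in WTPR and 2 lower. Against vector, WTPR had 1 higher and 23 lower (camera with an estimated correlation, unadjusted p = 3.59e-04) and mCDPR 8 and 7 (p = 0.684), so the difference at the start goes with a low level in WTPR. With R5020, 12 were higher in mCDPR than in WTPR and 8 lower (camera with an estimated correlation, p = 0.446). Within the lines, R5020 was followed by 9 higher and 15 lower genes in WTPR (camera with an estimated correlation, unadjusted p = 0.109, not called) and 6 and 25 in mCDPR (unadjusted p = 6.34e-04). The lower start in WTPR may be part of the difference in response.

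Levels of genes on some chromosome arms differed between the lines. The spread of the arm medians was 4.54 times the permuted mean for WTPR against vector with vehicle and 1.94 times for mCDPR against vector, so gains or losses of arms in both lines cannot be told apart from other causes. The smaller ratio missed the factor set beforehand (at least 2 times the 1.58 of the R5020 response in WTPR) and is close to the 1.92 of the R5020 response in mCDPR, where copies cannot differ. In WTPR against vector the medians were -0.23 on 12q (251 lower and 31 higher of 567 genes), -0.36 on 20p (72 and 2 of 122), -0.21 on 20q (118 and 17 of 269) and -0.23 on 21q (70 and 13 of 165), and in mCDPR against vector 0.04, 0.008, 0.009 and -0.04. The largest median in mCDPR against vector was that of 2p, picked after its value was seen, -0.14 (132 lower and 40 higher of 382), against -0.08 in WTPR. The arms 12q, 20p, 20q and 21q hold 7.64% of the genes and 23.4% of the lower ones. In the R5020 arrays the 8 medians against vector and mCDPR were at or below -0.224. These arrays come from the same clones and R5020 in WTPR moved these arm medians by -0.041 at most, so any lasting difference of the clone would repeat there. Against all genes with vehicle, the arm medians ran from -0.216 to -0.371, from -0.193 to -0.339 with median scaling, from -0.162 to -0.252 with an offset of 50, and from -0.11 to -0.194 without background correction. The size therefore depends on the background correction, shrinking by a factor of more than 1.5 without it, while the direction held for each arm, which argues against normalization as the whole cause. Fewer copies of these arms in the WTPR clone cannot be told apart from other lasting differences of it, since DNA was not measured.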
